A study of Yarrowia lipolytica with 63 samples.

How the data were processed

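RNA from cultures of the yeast Yarrowia lipolytica was measured on 63 single-colour (Cy3) Agilent arrays in 21 groups of 3. Strain Af4 carries a polyunsaturated fatty acid (PUFA) synthase and, per the labels, makes docosahexaenoic acid (DHA); strain Po1h does not. Condition C1 was Af4 with 20 g/L glycerol and 1.3 g/L phosphate (carbon to phosphate ratio 41.3), C2 was Af4 with 20 g/L glycerol and 0.65 g/L phosphate (ratio 95.2), C3 was Af4 with 40 g/L glycerol and 0.65 g/L phosphate (ratio 190.4), and C4 was Po1h in the medium of C2. All had 5 g/L ammonium sulfate, and the carbon to nitrogen ratio was 8.6, or 17.2 in C3. Phosphate levels and ratios stand as the series description gives them. The ratios of C1 and C2 differ by more than the phosphate levels do, and the sources used here do not give the reason. C1, C2 and C4 were sampled at 6, 24, 48, 72 and 96 h, and C3 at 6, 20, 48, 72, 96 and 120 h. Per the labels 6 h, and 20 h in C3, were exponential growth and all other times were stationary phase. Comparisons of exponential with stationary times therefore also compare growth phases, which cannot be told apart from DHA production. Groups were taken from the labels and never from the values. The labels do not say that the replicates of a group came from separate cultures, so every p-value measures the spread between these samples.

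Per the file headers, the scanner files of the authors hold an intensity for each spot (a background-corrected processed signal, a median signal and a local background), in linear units. Per the file headers they also hold other columns, which are flags for spots well above background, saturated spots and non-uniform outlier spots. The deposited value table is in log2 units, and it was checked to equal the scanner values after subtraction of each array's 75th percentile and centring of each probe (lowest correlation 1.0000 across 19326 probes, median absolute difference 0.0028). The deposited fold-change tables of the authors are in log2 units relative to 6 h, and 4 of their columns, which hold no values, were not used. Those tables hold locus tags, and the arrays hold feature names. Each tag was paired with a feature where differences between times after 6 h on the arrays gave those of the table within 1e-05. Not every later time was used in each condition, and the labelled 6 h means were not used. These means gave the table's 6 h baseline for 1 of 3189 genes in C1, 4 of 3818 in C2 and 3755 of 3755 in C4. The pairing matched 4762 of 4763, 5727 of 5728 and 5149 of 5150 table lines in the conditions whose columns all hold values. It matched 0 after a shift of the values by 0.01. Of 6465 features 17 are the transgenes, 5998 took a tag and 450 took none. All 5977 nuclear tags lay on the chromosome that the feature's own name gives. The genome build, start and end of the genes are not given in the sources used here, and the letter after the tag's 0 digit stands in for the chromosome. The tags of URA3, ICL1 and KGD1 met no feature and were not analysed here.

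Of the 57978 spots that are not controls, those marked as outliers were left out (median 1099 and at most 1236 per array). The log2 processed signal was averaged over the 3 spots of a probe, scaled by the array's 75th percentile and averaged over the probes of a gene (3 probes for 6408 genes). A gene was tested if at least 1 of its probes was well above background on all 3 arrays of at least 1 group, which kept 6464 genes and left out 1. Between 93.9% and 99.9% of spots were well above background, no spot was saturated, and the 75th percentile of the arrays lay between 9.39 and 13.51 on the log2 scale. The number of arrays limits the precision.

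The variance between each pair of arrays was compared with the spread between spots of a probe (median SD 0.068 log2) in 20 brightness bins. Of 63 pairs within a group 2 differed by less than that (C1 96 h A and B, ratio 0.67; C2 96 h B and C, ratio 0.95), and each pair was averaged and counted as 1 replicate, which left 61. The ratio had a median of 12.5 within groups and 217 between groups. Pairs of libraries from different groups that differed by less than the spot noise kept their labels.

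A linear model with 1 mean per group was fitted to all genes with limma 3.58.1 (empirical Bayes, R 4.3.3), and 17 comparisons were read from it. A gene passed a comparison with a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 difference of at least 1. Fixed gene lists were tested with limma's camera (preset correlation), adjusted over the 187 list tests (11 lists with enough members, 17 comparisons), and again with a correlation estimated from the data. Lists of fewer than 3 genes (glycerol uptake, branched-chain amino acid breakdown) have counts only. Lists defined by keywords in gene descriptions were not used, since the sources used here hold no descriptions. A list of 12 mitochondrially encoded genes was chosen after the files were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.

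The comparisons, gene lists, thresholds, most alternatives and the rule for naming genes were chosen before the data were examined. By that rule the genes named are the 10 largest rises and falls with an informative name in the main comparisons (3 in the others) whose arrays do not overlap; members of the fixed lists may be named with their values, and counts of 5 or fewer are named in full. Where a gene falls outside this rule the text says so. The replicate letters were checked for pairing: 3 of 32 pairs of groups had correlations of all 3 letters above 0.1, and the median was -0.14, so a block by letter was run as an alternative and the main model is unpaired.

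Alternatives were quantile scaling, the percentile of probes well above background on all arrays (17681 probes), normexp background correction (offset 50) on the median signal (the mean signal is not in the files), the brightest probe per gene, the authors' value table, no filter on dim genes, no minimum fold, only the groups compared, replicate letter, slide and scan day as blocks, and leaving out each library. Added after the data were seen were 63 separate arrays, the late comparisons without 96 h, C2 alone from 72 to 96 h, and a fit without the libraries of 6 to 72 h that correlate most with a library of another group. The arrays came from 8 slides and 4 scan days. On simulated data, changes of 1.5 and 3 log2 were planted in 100 genes each (6464 genes, limma). In the C2 time comparison 99% and 100% were recovered with 2 false calls. In the late strain comparison 100% and 100% were recovered with 0 false calls. The simulated noise was independent between arrays, while real arrays of 1 slide deviated together (correlation 0.518). The simulation therefore does not give the number of false calls in these data.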

Results

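The arrays cover Af4 in 3 media (C1, C2, C3) and Po1h in 1 medium (C4), with 3 libraries per group. In 2 groups a pair of libraries differed by less than the noise between spots and counted as 1, so n = 2 in C1 96 h and C2 96 h, and the number of arrays limits the precision. Values are log2 differences ± SE from limma, or log2 levels relative to the array's 75th percentile ± SD. A gene is said to rise, fall or differ only where it passed the test.

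The 17 PUFA synthase transgenes (domains of Pfa1, Pfa2 and Pfa3, and the phosphopantetheinyl transferase gene Ppt, which activates carrier proteins) were low at 6 h and high from 24 h in Af4. Most are segments of Pfa2 or Pfa3, so the 17 are not separate genes. A count of genes that includes them counts each segment as 1. The preset correlation treats the segments as nearly independent, so the p-values it gives this list are likely too small. The median level of the 17 in C2 was -1.37 ± 0.22 at 6 h, 4.94 ± 0.13 at 24 h and 4.99 ± 0.08 at 72 h (SD, n = 3). In C1 it was -1.65 ± 0.36 at 6 h and 4.60 ± 0.64 at 72 h, and in C3 it was 0.20 ± 0.29 at 6 h, 2.48 ± 0.06 at 20 h and 4.65 ± 0.43 at 72 h. In Po1h, which lacks them per the labels, the median was -8.02 ± 0.18 at 6 h and -7.75 ± 0.73 at 72 h, with 4 and 5 of the 17 not above background. The libraries labelled C1 96 h had -7.04 ± 0.12 (n = 2), and the libraries labelled C4 96 h had 4.40 ± 0.17 (n = 3), each at the level of the other strain. The highest of the libraries labelled C1 96 h was -6.72, the lowest C1 library of 24 to 72 h was 3.85, the highest C4 library of 6 to 72 h was -6.92 and the lowest of the libraries labelled C4 96 h was 4.20. The authors' table for C1 gives the transgenes a median of 5.35 above 6 h at 96 h, although 3172 of the 3189 genes compared equal the arrays labelled C1 96 h within 1e-05. Labels were kept as given, and the comparisons that use these libraries are repeated without 96 h.

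**Figure D1:**
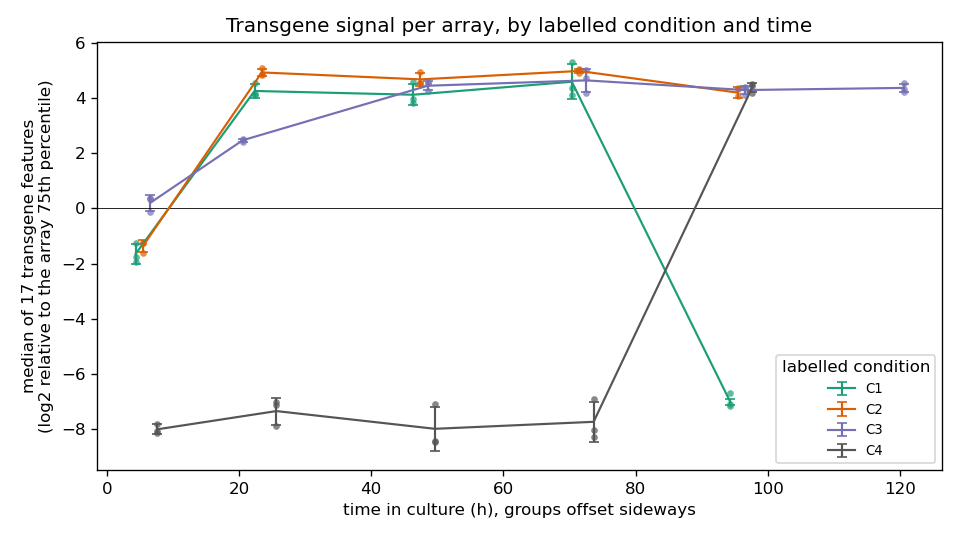
Median log2 level of the 17 transgenes relative to the array's 75th percentile, against hours of culture, by condition; points are libraries and lines join group means. The libraries labelled C1 96 h lie near -7.04 and those labelled C4 96 h near 4.40.

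Per the labels C2 was in exponential growth without DHA at 6 h, and in stationary phase at its highest DHA rate at 72 h. Between these times many genes of fatty acid breakdown and the transgenes rose in C2. Of the acyl-CoA oxidase genes, which start peroxisomal beta-oxidation, POX4 (YALI0E27654g) rose by 7.49 ± 0.37, POX6 (YALI0E06567g) by 6.49 ± 0.18 and POX1 (YALI0E32835g) by 5.39 ± 0.17 (SE, n = 3 and 3). Of the 18 genes of breakdown and peroxisome 16 rose (adjusted p = 4.1e-06, 0.11 with an estimated correlation). YAS1 and YAS2, regulators of alkane and fatty acid genes, rose by 4.39 ± 0.28 and 3.98 ± 0.10, and FAA1, which activates fatty acids, by 3.28 ± 0.11. All 17 transgenes rose, Pfa3_AGPAT most with 7.73 ± 0.34 (list adjusted p = 5.5e-07, 0.44 with an estimated correlation).

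In C2 8 of 12 sterol genes and 5 of 7 acetyl-CoA genes fell over the same time. ERG13 (YALI0F30481g), the synthase of hydroxymethylglutaryl-CoA, fell by 3.95 ± 0.09, and the thiolase gene ERG10 (YALI0B08536g) fell by 2.65 ± 0.11. Of the 12 mevalonate and ergosterol genes 8 fell (adjusted p = 0.010, 0.35 with an estimated correlation). ACL2 (YALI0D24431g), a subunit of ATP citrate lyase that makes cytosolic acetyl-CoA, fell by 3.90 ± 0.13, and MAE1 (YALI0E18634g), malic enzyme, fell by 4.74 ± 0.19. Of 10 fatty acid synthesis genes 5 fell (MAE1, ACL2, FAD2, FAS1 and ELO1) and 2 rose, OLE1 by 1.98 ± 0.12 and ELO2 by 1.22 ± 0.14 (adjusted p = 0.032, 0.44 with an estimated correlation, and 0.077 under quantile scaling). Of 7 acetyl-CoA supply genes, which include both ACL genes of the synthesis list, 5 fell (ACL2, LAT1, LPD1, PDA1 and PDB1) and ACS2 rose by 2.57 ± 0.12 (adjusted p = 0.032, 0.46 with an estimated correlation, and 0.054 under quantile scaling).

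Genes of central carbon use split in C2. In the TCA cycle SDH2 and SDH1, subunits of succinate dehydrogenase, rose by 5.10 ± 0.10 and 4.10 ± 0.12 and aconitase ACO1 by 4.13 ± 0.14, while fumarase FUM1 (YALI0C06776g) fell by 4.57 ± 0.24 and IDH1 (YALI0E05137g), a subunit of isocitrate dehydrogenase, fell by 3.91 ± 0.15. Citrate synthase CIT1 (YALI0E02684g) fell by 2.68 ± 0.19 and malate dehydrogenase MDH1 (YALI0D16753g) fell by 3.00 ± 0.19. The list had 3 rises and 6 falls of 12 (adjusted p = 0.42, 0.76 with an estimated correlation). In glycolysis PGK1 (YALI0D12400g), phosphoglycerate kinase, fell by 3.78 ± 0.21. Of 10 glycolysis genes 7 fell while PFK1 rose by 1.57 ± 0.09 (adjusted p = 0.028, 0.46 with an estimated correlation, and 0.054 under quantile scaling). In the glyoxylate cycle and gluconeogenesis PCK1, MLS1, MLS2 and PYC1 rose, malate synthase MLS1 by 2.52 ± 0.15 and PCK1 by 2.79 ± 0.17, and FBP1 (YALI0A15972g) fell by 3.29 ± 0.12. The list had 4 rises and 1 fall of 5 (adjusted p = 0.29, 0.46 with an estimated correlation). DGA1, which makes storage triglyceride, rose by 3.73 ± 0.13 with GPD1 and LRO1, 3 of 8 glycerolipid genes (adjusted p = 0.057, 0.44 with an estimated correlation, and 0.045 under quantile scaling). In the pentose phosphate pathway RPE1 rose by 3.40 ± 0.14 and TAL1, TKL1, ZWF1 and SOL3 fell, 4 of 6 (adjusted p = 0.13, 0.49 with an estimated correlation). GUT2 (1.13 ± 0.12, glycerol catabolism, 1 of 2) and BAT1 (1.29 ± 0.17, branched-chain amino acids, 1 of 2) rose. Of 12 mitochondrially encoded genes 10 rose (adjusted p = 0.24, 0.78 with an estimated correlation). In every list of C2 the counts were the same when adjusted over the list alone (16 of 18 breakdown genes, for example).

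Over all genes 3410 of 6464 differed in C2 between 72 h and 6 h, 2057 higher and 1353 lower. The same comparison gave 3512 genes in C1 (2140 higher, 1372 lower), 2932 in C3 (1778 higher, 1154 lower) and 3122 in Po1h (1842 higher, 1280 lower). POX4 rose by 7.79 ± 0.37 in C1, 9.40 ± 0.37 in C3 and 6.97 ± 0.37 in Po1h, and ACL2 fell in each (-3.98 ± 0.13, -2.99 ± 0.13 and -3.72 ± 0.13 in the same order; n = 3 and 3). ERG13 had -3.77 ± 0.09 in C1, -3.29 ± 0.09 in C3 and -3.42 ± 0.09 in Po1h. Of the 18 breakdown genes 15 rose in each of C1 (adjusted p = 7.6e-06, 0.12 with an estimated correlation), C3 (3.3e-06, 0.11) and Po1h (2.0e-05, 0.12). Of the 12 sterol genes 9 fell in C1 (adjusted p = 0.0021, 0.25 with an estimated correlation), 10 in C3 (7.6e-05, 0.12) and 9 in Po1h (0.00036, 0.16). In Po1h 2 of 17 transgene features passed, Pfa3_AGPAT with 1.58 ± 0.34 and Pfa1, which was not above background at either time, so that its change is not given (list adjusted p = 0.39, 0.87 with an estimated correlation). Under quantile scaling the direction of that list turned without passing (adjusted p = 0.096). In all 4 conditions 1276 genes rose, against 53.4 expected if the conditions were independent, and 892 fell, against 10.2. Another 20 genes rose in one and fell in another. The conditions are not fully independent, since C1 6 h C and C2 6 h C differed by less than the noise between spots. In all 4 conditions the arrays were also fainter at 72 h than at 6 h. Their mean 75th percentile went from 12.84 to 10.64 in C1, 12.93 to 10.97 in C2, 12.47 to 11.69 in C3 and 12.58 to 11.26 in Po1h. All 17 transgene features had positive values in Po1h, with a median of 0.71. Whether fainter arrays add to the shared rises was not tested. These list counts were the same when adjusted over the list alone (15 of 18 breakdown genes).

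**Figure D2:**
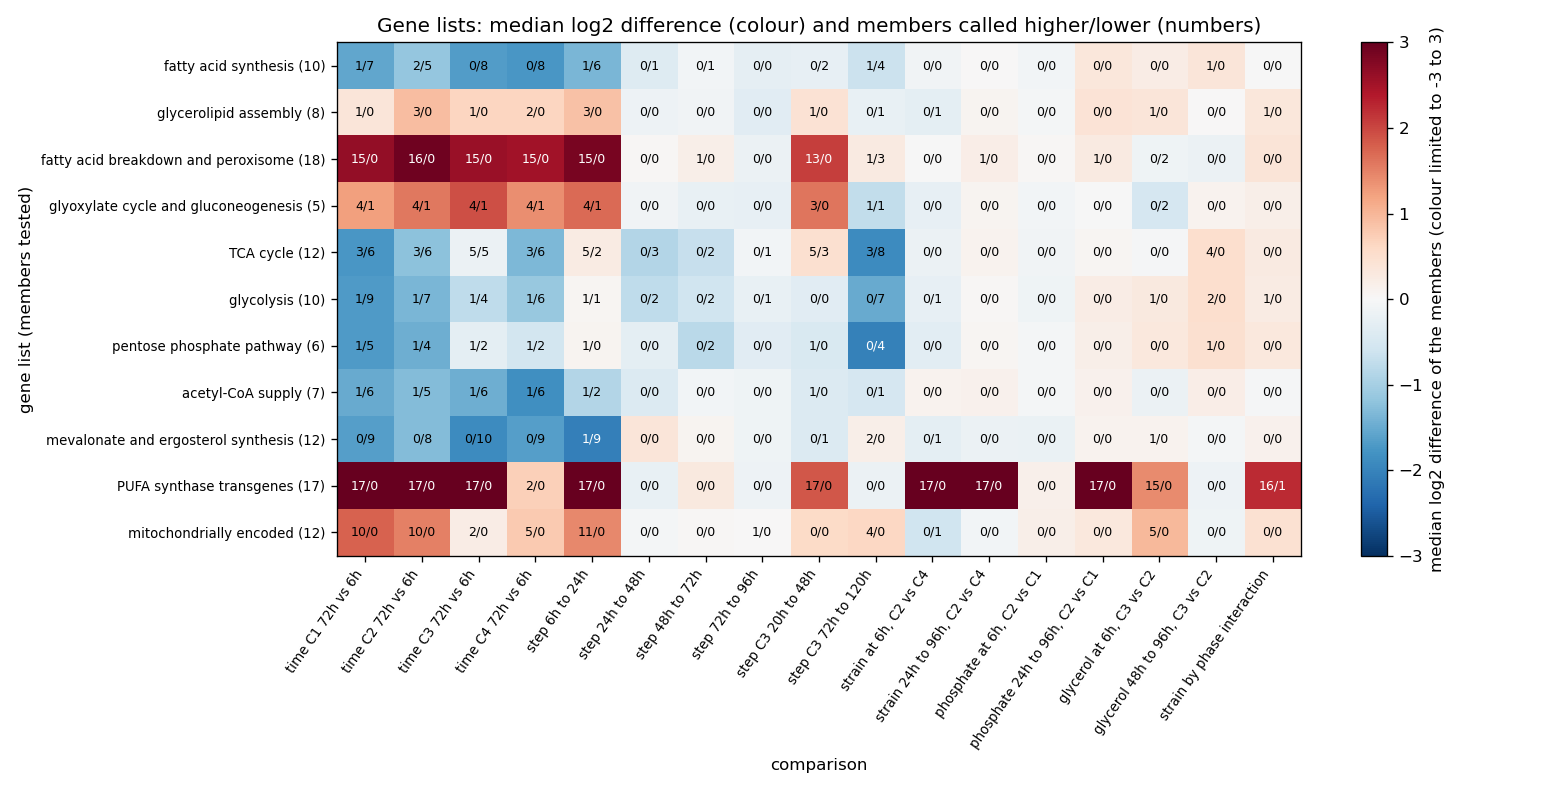
Median log2 difference of each gene list by comparison, from limma, as colour limited to -3 to 3, with the numbers of members that passed as higher and lower. The breakdown list had a median of 2.93 in C2 between 72 h and 6 h and the sterol list -1.29.

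From 6 to 24 h, in the mean of C1, C2 and C4 (n = 9 and 9), 15 of 18 breakdown genes rose and 9 of 12 sterol genes fell. POX4 rose by 6.37 ± 0.21 and POX6 by 5.49 ± 0.10, while ERG13 (-4.32 ± 0.05), ERG10 (-2.96 ± 0.06) and FBP1, fructose bisphosphatase (-2.89 ± 0.07), fell. Of the 18 breakdown genes 15 rose (adjusted p = 8.0e-06, 0.12 with an estimated correlation), and of the 12 sterol genes 9 fell and ERG8 rose by 1.25 ± 0.13 (adjusted p = 0.00092, 0.21 with an estimated correlation). The counts were the same when adjusted over the list alone (15 and 9). In all 3193 genes passed, 1866 higher and 1327 lower.

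From 24 to 48 h DHA synthesis began in Af4 per the labels. The mean of C1, C2 and C4 also holds Po1h, which makes none, so its changes are not particular to DHA synthesis. In that mean 254 genes passed (141 higher, 113 lower, n = 9 and 9). The balance turned after normexp (135 genes, 41.5% higher) and under quantile scaling (188 genes, 87 higher, 101 lower), and within 1 scan day 476 genes passed (357 higher, 119 lower). IDH1 (-1.51 ± 0.09), MDH1 (-1.15 ± 0.11) and MDH2 (YALI0E14190g, -1.28 ± 0.14) fell, 3 of 12 TCA genes (adjusted p = 4.7e-08, 0.053 with an estimated correlation). In glycolysis GPM1, phosphoglycerate mutase, fell by 1.16 ± 0.16 and TDH1 (YALI0C06369g) fell by 1.21 ± 0.11, 2 of 10 (adjusted p = 7.0e-06, 0.14 with an estimated correlation). Under quantile scaling TDH1 had -0.97, just short of the minimum change of 1 log2. From 48 to 72 h 166 genes passed in the same mean (36 higher, 130 lower). POX1 rose by 1.12 ± 0.10, the only one of 18 breakdown genes (adjusted p = 0.015, 0.41 with an estimated correlation). In glycolysis GPM1 (YALI0B02728g) fell by 1.14 ± 0.16 with PGK1, 2 of 10 (adjusted p = 8.6e-07, 0.12 with an estimated correlation). FUM1 fell by 1.02 ± 0.14 and CIT1 fell by 1.01 ± 0.11 (2 of 12 TCA genes, adjusted p = 0.0030, 0.35 with an estimated correlation). ZWF1 and TAL1 (YALI0F15587g) of the pentose phosphate pathway fell, ZWF1 by -1.01 ± 0.10 (2 of 6, adjusted p = 0.00044, 0.13 with an estimated correlation). TAL1 went from -1.002 to -0.97 under quantile scaling, just short of the minimum of 1. The counts were the same when adjusted over the list alone (3 TCA genes at 24 to 48 h and 2 at 48 to 72 h).

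From 72 to 96 h C1 and C2 came into the plateau of DHA per the labels. The values are the mean of C1, C2 and C4 (n = 9 and 7), which also holds Po1h. The isocitrate dehydrogenase gene IDP2 (YALI0F04095g) fell by 1.14 ± 0.11 and GPM1 fell by 1.06 ± 0.17. The mitochondrial genes nd3 and cox1-i6 rose by 1.15 ± 0.16 and 1.00 ± 0.23. IDP2 was the only TCA gene of 12 to pass (adjusted p = 0.18, 0.63 with an estimated correlation), and the count was 1 also when adjusted over the list alone. In all 613 genes passed, 568 higher and 45 lower, and 260 passed under quantile scaling (57.3% higher) and 79 after normexp (70.9% higher). C2 alone, without the libraries labelled C1 96 h and C4 96 h, gave 1181 genes (593 shared with the mean). There MAE1 rose by 2.21 ± 0.22, FUM1 by 1.08 ± 0.27 and PGK1 by 1.07 ± 0.23 (n = 3 and 2), while BAT2 (-1.08 ± 0.23) and the transgene Pfa3_AGPAT (-1.05 ± 0.38) fell. C2 96 h B and C, counted as 1, differed from C3 96 h A by less than the noise between spots. IDP2 (-0.66 ± 0.19), GPM1 (-0.77 ± 0.31) and cox1-i6 (0.82 ± 0.42) did not reach the minimum of 1 there, and 80.2% of the genes were higher. All libraries of 96 h were scanned on a day without libraries of 72 h, so time and scan day cannot be told apart here.

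In C3, with more glycerol, 13 of 18 breakdown genes rose between 20 and 48 h. POX4 rose by 7.14 ± 0.37, POX6 by 6.37 ± 0.18 and POX1 by 4.99 ± 0.17, with PCK1, which feeds gluconeogenesis, at 4.23 ± 0.17 and MLS1 at 3.95 ± 0.15 (n = 3 and 3). FAD2 (YALI0B10153g), the delta-12 desaturase gene, fell by 1.90 ± 0.11, and IDH1 (-1.90 ± 0.15) and ERG1 (YALI0E15730g, squalene epoxidase, -1.40 ± 0.23) fell too. Of 18 breakdown genes 13 rose (adjusted p = 5.9e-10, 0.019 with an estimated correlation), and PCK1, MLS1 and MLS2 made 3 of 5 glyoxylate genes (adjusted p = 0.024, 0.12 with an estimated correlation). All 17 transgenes rose (adjusted p = 1.6e-05, 0.46 with an estimated correlation), and the counts were the same when adjusted over the list alone (13 and 17). In all 1391 genes passed, 746 higher and 645 lower.

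From 72 to 120 h in C3 many genes of glycolysis and the TCA cycle fell, and 3 TCA genes rose. The falls were -3.55 ± 0.27 for GPM1, -3.47 ± 0.24 for MDH2, -3.47 ± 0.19 for CIT1, -3.44 ± 0.24 for FUM1 and -3.25 ± 0.21 for PGK1 (n = 3 and 3). Of 10 glycolysis genes 7 fell (adjusted p = 5.7e-06, 0.14 with an estimated correlation). Of 12 TCA genes 8 fell and ACO1, SDH1 and SDH2 rose (adjusted p = 0.0043, 0.35 with an estimated correlation). In the pentose phosphate pathway GND1, TAL1, TKL1 and ZWF1 fell, 4 of 6 (adjusted p = 0.0014, 0.16 with an estimated correlation). The mitochondrial features cox1-i6, nd3 and cox1-i5 rose by 2.35 ± 0.37, 2.05 ± 0.26 and 2.03 ± 0.29. Under quantile scaling cox1-i6 had 1.01, and cox1-i5 had 0.99 and no longer passed the minimum of 1. The list counts were the same when adjusted over the list alone (7 and 8). In all 1976 genes passed, 1207 higher and 769 lower. The libraries of 120 h share no scan day with those of 72 h, so time and scan day cannot be told apart here. C3 120 h B differed from the library labelled C4 96 h C by less than the noise between spots.

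**Figure D3:**
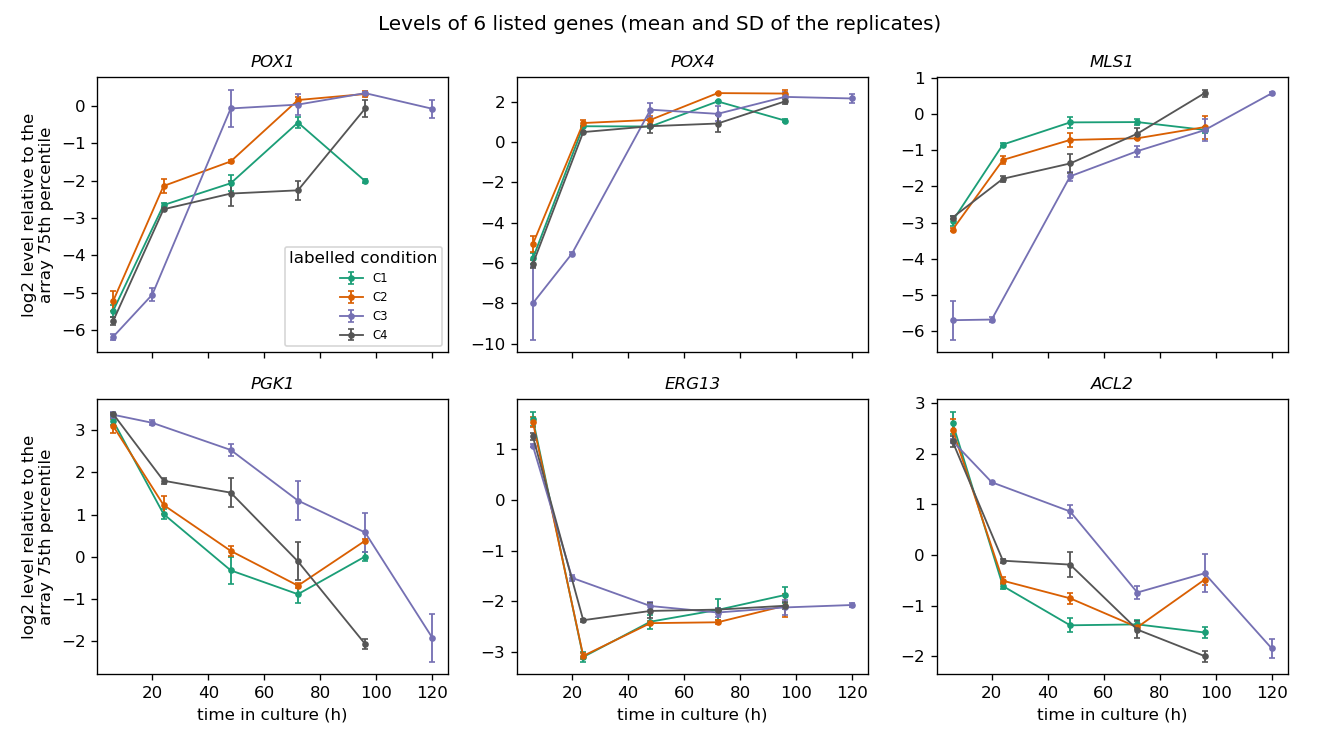
Log2 level of 6 listed genes relative to the array's 75th percentile against hours of culture, by condition; points are group means and bars are the SD of the replicates. POX1 in C2 goes from -5.23 at 6 h to 0.17 at 72 h and PGK1 from 3.10 to -0.68.

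Af4 and Po1h in the same medium (C2 against C4) differed most in the transgenes. At 6 h the transgenes were a median of 6.00 log2 higher in Af4 (3.31 to 11.3, with 4 of 17 set at the Po1h background), and they were 8.50 to 15.2 higher at 24 h and 8.75 to 14.1 at 72 h (2 and 5 of 17 set at the background). Pfa1 was at least 2530-fold higher at 6 h, Pfa2_ACP3 466-fold and Ppt 61.3-fold (n = 3 and 3; 17 of 17 transgenes passed, adjusted p = 2.2e-61, 0.0028 with an estimated correlation, 17 also when adjusted over the list alone). In C2 at 6 h ERG8 (YALI0E06105g), phosphomevalonate kinase, was lower than in Po1h (-1.32 ± 0.22), as were the sterol acyltransferase gene ARE1 (YALI0F06578g, -1.30 ± 0.22), GPM1 (-1.19 ± 0.27), BAT2 (-1.12 ± 0.21) and cox3 (-1.06 ± 0.44). C3 6 h, also Af4, stood at -3.13 for ERG8, -0.21 for ARE1, 2.61 for GPM1 and 2.03 for cox3, against -3.36, -0.69, 2.27 and 1.33 in Po1h, so these 4 are not shown to be a trait of the strain. All 3 libraries of C3 6 h share a slide with Po1h 6 h B and C, and no library of C2 6 h is on it. ERG8 had -0.77 under quantile scaling and no longer passed the minimum of 1, and cox3 did not pass adjusted over the list alone (0 of 12 mitochondrial genes; list adjusted p = 0.68, 0.92 with an estimated correlation). In all 680 genes passed (341 higher, 339 lower), with 144 under quantile scaling and 229 after normexp. The balance depends on the setting: 10% were higher after normexp and 76.7% of 464 genes with the slide as a random block, against 50.1%. By limma 25 (23 higher, 2 lower) passed within the 1 slide that holds both groups (3 libraries), where Po1h has only 1 library and its spread is taken from the others.

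Over 24 to 96 h 37 features differed between the strains: 17 transgene features, 15 other genes higher in Af4 and 5 lower (n = 11 and 12). POX1 was higher by 1.07 ± 0.09, the only one of 18 breakdown genes to pass, while the list as a whole lay a median of 0.19 higher (adjusted p = 1.3e-10, 0.016 with an estimated correlation; 1 also when adjusted over the list alone). The transgenes had adjusted p = 3.1e-122 (8.5e-06 with an estimated correlation, 17 of 17). The 5 lower genes, named after their values were seen, were YALI0D18084g (-2.66), YALI0C05885g (-1.68), YALI0D03740g (-1.28), YALI0F28193g (-1.27, turned to 0.68 without 96 h) and YALI0C15488g (-1.25). The libraries labelled C4 96 h carry the transgenes of Af4, and without 96 h 88 genes passed (17 transgenes, 26 others higher, 45 lower; 31 shared). There POX1 was 1.30 ± 0.10 higher, and MAE1 was lower at -1.16 ± 0.11.

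The change of the strain difference from 6 h (exponential) to the later, stationary times passed for 637 genes (254 higher, 383 lower). It compares growth phases and is not particular to DHA production. Among the transgenes 16 passed as larger later, with Pfa3_DH2 at 3.80 ± 0.32, and Pfa1 as smaller (-1.06 ± 0.23; adjusted p = 4.4e-13, 0.26 with an estimated correlation; 16 also when adjusted over the list alone). Pfa1 was not above background in Po1h at 6 h and turned to 1.20 under quantile scaling. BAT2 with 1.26 ± 0.23, ARE1 with 1.13 ± 0.25 and GPM1 with 1.06 ± 0.31 rose relative to Po1h, and cox1-i6 fell (-1.08 ± 0.42, turned to 0.19 under quantile scaling). The difference at 6 h is subtracted in these values. At 6 h ARE1 (-1.30), GPM1 (-1.19) and BAT2 were lower in C2 than in Po1h. For ARE1 and GPM1 that was not shown to be a trait of the strain, so neither are these rises. Without 96 h 750 genes passed, with all 17 transgenes larger later (Pfa3_DH2 at 6.67 ± 0.36 and Pfa1 at 3.02 ± 0.26). There ARE1 had 0.98 ± 0.26, just short of the minimum of 1, and GPM1 (0.63 ± 0.34) and cox1-i6 (-0.76 ± 0.42) did not pass. Listed genes that passed only there were DGA1 (1.22 ± 0.15), SDH2 (1.04 ± 0.10), atp9 (1.02 ± 0.31), SDH1 (1.01 ± 0.13), FUM1 (-1.13 ± 0.22) and MAE1 (-1.11 ± 0.22). Quantile scaling gave 187 genes and normexp 179, and the balance turned, with 56.2% and 93.9% higher against 39.9%, and 22.1% with the slide as a random block. Of the splits of the libraries 8 of 100 gave as many genes as the labels.

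With less phosphate (C2 against C1) 0 genes passed at 6 h by limma, with 363 at an unadjusted p under 0.05 (n = 3 and 3). By camera the sterol list lay lower in C2 (median -0.21, adjusted p = 0.0015, 0.24 with an estimated correlation). The transgene list lay higher (0.16, adjusted p = 0.023, 0.72 with an estimated correlation). The TCA list lay lower (-0.12, adjusted p = 0.042, 0.46 with an estimated correlation, and 0.066 under quantile scaling). C1 6 h C and C2 6 h C differed by less than the noise between spots, and without the libraries closest to another group 48 genes passed, and 14 without C1 6 h C alone. The authors' own tables leave C1 6 h C out of the 6 h mean of C1 (3189 of 3189 genes equal the mean of A and B) and hold it in that of C2 (3818 of 3818 genes), so the count of 0 rests on a library that they placed with C2. Within the slide that holds A and C of both groups (4 libraries) 0 passed by limma, with 3 at an unadjusted p under 0.05. That slide carries the pair C1 6 h C and C2 6 h C, so its 0 is not separate evidence. Another slide holds B of both groups, with 1 library each, and could not be tested alone. Over 24 to 96 h 36 features passed (n = 11 and 11), of which 17 were the transgene features (adjusted p = 2.0e-36, 0.032 with an estimated correlation, 17 also when adjusted over the list alone). These rest on the libraries labelled C1 96 h: without 96 h 48 genes passed by limma (43 higher, 5 lower), none of them a transgene, and 4 were shared with the 36. The brightest probe gave 69 genes, and 113 passed without the libraries of 6 to 72 h closest to another group. POX1 was higher by 1.01 ± 0.09 in C2, the only one of 18 breakdown genes (adjusted p = 0.0097, 0.36 with an estimated correlation; 1 also when adjusted over the list alone), and had 0.85 under quantile scaling and 0.57 ± 0.10 without 96 h, short of the minimum of 1. The 2 lower genes, named after their values were seen, were YALI0F28193g (-1.72, and 0.02 without 96 h) and YALI0C05885g (-1.20, and -0.58 without 96 h).

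With more glycerol (C3 against C2) 4 breakdown and glyoxylate genes were lower at 6 h. POX4 differed by -2.94 ± 0.37 (-1.80 under quantile scaling), POX6 by -1.47 ± 0.18, MLS1 (YALI0D19140g) by -2.50 ± 0.15 and PCK1 by -1.34 ± 0.17 in C3 (n = 3 and 3). MLS1 and PCK1 made 2 of 5 glyoxylate genes (adjusted p = 0.0055, 0.053 with an estimated correlation) and POX4 and POX6 2 of 18 breakdown genes (adjusted p = 0.092, 0.50 with an estimated correlation). Of the transgenes 15 of 17 were higher in C3, Pfa2_DH1 by 1.97 ± 0.32 and Pfa2_KR by 1.89 ± 0.26 (adjusted p = 7.6e-05, 0.49 with an estimated correlation). ARE1 (1.78 ± 0.22), ERG8 (1.55 ± 0.22), GPM1 (1.52 ± 0.27) and the mitochondrial gene nd4 (1.93 ± 0.55) were higher too. At 6 h ARE1 (-1.30), ERG8 (-1.32, and -0.77 under quantile scaling) and GPM1 (-1.19) were also lower in C2 than in Po1h in the same medium. Po1h 6 h B and C share a slide with all libraries of C3 6 h, and no library of C2 6 h is on it. The differences of ARE1, ERG8 and GPM1 are therefore not shown to follow glycerol. The counts were the same when adjusted over the list alone (2 and 15), except that 6 in place of 5 of the mitochondrially encoded genes passed (adjusted p = 0.20, 0.76 with an estimated correlation). In all 1071 genes passed (598 higher, 473 lower), with 320 under quantile scaling and 450 after normexp. The balance depends on the setting: 93.6% were higher after normexp and 30.7% of 717 genes with the slide as a random block, against 55.8%. C3 6 h shares no slide and no scan day with C2 6 h, so there is no value within a batch.

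Over 48 to 96 h 8 listed genes of central carbon use were higher in C3 than in C2. MAE1 was higher by 1.95 ± 0.12, PGK1 by 1.53 ± 0.13, MDH2 by 1.38 ± 0.14, FUM1 by 1.32 ± 0.14, CIT1 by 1.11 ± 0.11, MDH1 by 1.04 ± 0.12, GPM1 by 1.04 ± 0.16 and ZWF1, which opens the pentose phosphate pathway, by 1.00 ± 0.10 (n = 9 and 8). CIT1, FUM1, MDH1 and MDH2 made 4 of 12 TCA genes (adjusted p = 0.098, 0.54 with an estimated correlation, and 0.011 under quantile scaling) and PGK1 and GPM1 2 of 10 glycolysis genes (adjusted p = 0.021, 0.46 with an estimated correlation). The counts were 4 and 2 also when adjusted over the list alone. In all 274 genes passed, 222 higher and 52 lower, with 176 after normexp and 69.0% higher under quantile scaling against 81.0%. At 96 h C3 A differed from each of C2 B and C by less than the noise between spots. Every library of both groups at 96 h correlated most with a library of the other group. At 48 and 72 h alone 681 genes passed (522 higher, 159 lower, 274 shared). There MAE1 had 2.87 ± 0.13, PGK1 2.20 ± 0.13 and FUM1 1.91 ± 0.13.

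Within scan days that hold both groups, the comparison of 72 h with 6 h gave 3763 and 3508 genes in C1 (3 libraries each, with 1 library in an arm, so that its spread is taken from the others), 3409 in C2 (5 libraries), 2899 in C3 (5 libraries) and 3134 in Po1h (4 libraries). The steps gave 3261 genes from 6 to 24 h, 476 from 24 to 48 h, 112 from 48 to 72 h and 1442 in C3 from 20 to 48 h. The late comparisons have no scan day with all groups; with the scan day as a block they gave 36 genes for the strain, 29 for phosphate and 274 for glycerol. At 6 h the block gave 477 genes for the strain, 0 for phosphate (limma, 363 at an unadjusted p under 0.05 without the block) and 825 for glycerol. The median of all genes moved by 0.23, 0.28, 0.15 and 0.20 in the time comparisons of C1 to C4, by 0.21 from 6 to 24 h, by 0.11 in C3 from 72 to 120 h, by -0.16 for the strain at 6 h, by -0.11 for the late strain comparison and by 0.15 for glycerol at 6 h, and each gene's change stands relative to these. Of 187 list tests 65 passed with the preset correlation and 5 of them with an estimated correlation, and in 16, none of the 65, the test's direction differed in sign from the median or mean of the members.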

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

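The counts of other splits, the comparison of whole profiles of the 96 h libraries, and the tests of a loss of transgenes, of shared slides, of equal RNA levels, of wrong labels and of the scan day were chosen only after the result was seen. The test on genes that differ between the strains and the test of brightness were fixed first.

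A test of the difference itself (the strain difference of C2 and C4 at 24 to 96 h minus that at 6 h, limma) found 637 genes. The transgenes Pfa3_DH2 (3.80), Pfa3_AGPAT (3.61) and Pfa3_Pseudo_DH3 (3.51) were further above Po1h later, BAT2 (1.26), ARE1 (1.13) and GPM1 (1.06) moved up relative to Po1h, and cox1-i6 (-1.08) and Pfa1 (-1.06) had negative values. Both turned under quantile scaling (0.19 and 1.20), and Pfa1 was not above background in Po1h. Without 96 h, where the libraries labelled C4 carry the transgenes, Pfa3_DH2 had 6.67, Pfa3_AGPAT 6.31, Pfa3_Pseudo_DH3 6.59 and Pfa1 3.02, while ARE1 had 0.98, just short of the minimum of 1, and GPM1 (0.63) and cox1-i6 (-0.76) did not pass. For this count chance cannot be excluded, since 8 of 100 splits of the libraries gave as many genes and the highest other split gave 803, more than the labels. Such a count in another split points to a structure of the samples, and the fit holds the libraries labelled C4 96 h. The difference at 6 h is also subtracted in each value. ARE1 (-1.30) and GPM1 (-1.19) were lower in C2 than in Po1h at 6 h, which was not shown to be a trait of the strain.

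The libraries labelled C1 96 h lacked the transgenes and those labelled C4 96 h carried them. Loss of transgene expression in C1 as the whole cause is excluded, since the lowest of the libraries labelled C4 96 h stood at 4.2. An exchange of the labels of both groups is consistent with the 71 other genes that differ between the strains at 24 to 72 h: their strain difference correlated at -0.818 across genes with labelled C1 96 h minus labelled C4 96 h, 62 of 71 had the opposite sign, and genes are not independent replicates. In whole profiles 3 of 6 libraries were closer to the 72 h mean of the other condition. Those labelled C4 96 h were (0.908, 0.874 and 0.806 against 0.454, 0.379 and 0.307). Those labelled C1 96 h were not (0.756, 0.753 and 0.762 to their own against 0.435, 0.424 and 0.474). All 6 libraries thus correlated more with C1 72 h than with C4 72 h, whatever their label. That gives 3 of 6 under either labelling, so the whole profiles cannot decide on an exchange. With transgenes included, the library of another group closest to those labelled C1 96 h was C4 48 h C (0.735, 0.732 and 0.727). That is 1 library, and it reached only 0.695 with its own group. An exchange stays open together with a mix-up with C3 120 h. The libraries labelled C4 96 h correlated most with C3 120 h libraries (0.988, 0.985 and 0.999), and each C3 120 h library most with one of them. No biological explanation of both groups was tested.

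Of 1890 pairs of libraries from different groups 4 differed by less than the spread between spots: C1 6 h C and C2 6 h C (ratio 0.30), C3 96 h A with C2 96 h B (0.47) and C2 96 h C (0.91), and C3 120 h B with the library labelled C4 96 h C (0.67). A shared slide and time did not bring other pairs this close: 61 such pairs of different groups had a median ratio of 102 and a lowest of 10.6. Arrays of 1 slide still deviated together from their group means (correlation 0.518). On 1 slide, C3 120 h C and the library labelled C4 96 h A, of unlike times, had a ratio of 3.17. A part of the slide in the likeness therefore stays open. That the conditions gave the same RNA levels was judged over the 4 pairs together. It stays open for the other pairs, since the 4 are the most alike of 1890 and 1 of 63 pairs within a group was as alike as 0.912. For C1 6 h C and C2 6 h C the ratio of 0.30 lies below the lowest within a group (0.67). Replicates of C1 6 h had ratios of 18.4 to 29.7 and those of C2 6 h 22.7 to 24.8. These values argue against equal RNA levels as the whole cause for this pair. For the first pair the authors' own tables leave C1 6 h C out of the 6 h mean of C1 (3189 of 3189 genes) and hold it in that of C2 (3818 of 3818 genes). That 1 RNA was hybridised under 2 labels stays open too.

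From 72 to 96 h 568 genes rose and 45 fell. Wrong labels of C1 96 h and C4 96 h are not the whole cause, since in C2 alone 80.2% of the genes were higher. That does not exclude wrong labels in C2 96 h itself, whose libraries all correlated most with C3 96 h. A candidate explanation is that the fainter arrays of 96 h lift dim genes: the genes that rose stood at a median brightness percentile of 5.31 at 72 h, those that fell at 72.4, and 56 genes rose after normexp. The scan day cannot be told apart from time, since 0 libraries of 96 h were scanned on a day of 72 h libraries, and a change of the culture in the DHA plateau also stays open, untested.

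For comparisons of more than 6 libraries 100 splits were counted, and chance is an unlikely cause of a count that only the real split, 1 of 100, reached. This held from 6 to 24 h (3193 against 1613 in the highest other split), 24 to 48 h (254 against 70), 48 to 72 h (166 against 60), 72 to 96 h (613 against 228), for the late strain comparison (37 against 23), late phosphate (36 against 26) and late glycerol (274 against 146). For late phosphate 17 of the 36 genes are transgenes that rest on the libraries labelled C1 96 h, and 4 of the 36 passed without 96 h, so these splits also measure those labels. In the late strain comparison 17 of the 37 genes are transgenes, which Po1h lacks per the labels, so the real split is favoured by construction. The 15 higher and 5 lower other genes were not counted apart in the splits, and the highest other split had 23. For these other genes chance is not excluded. The late strain comparison also holds the libraries labelled C4 96 h. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real and highest other counts were 3512 and 287 for C1 over time, 3410 and 1 for C2, 2932 and 1 for C3, 3122 and 0 for C4, 1391 and 0 for C3 from 20 to 48 h, 1976 and 784 for C3 from 72 to 120 h, 680 and 0 for the strain at 6 h, 1071 and 29 for glycerol at 6 h, and 0 and 12 for phosphate at 6 h (limma, 363 at an unadjusted p under 0.05).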

How the results depend on the processing

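The settings without 96 h, C2 alone, 63 separate arrays and the fit without libraries closest to another group were chosen only after the result was seen. Of 224 alternative values of the 17 comparisons 190 lay within 1.5 times and 34 moved by more, and where nothing else is said the cause was not tested.

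Quantile scaling gave 260 genes from 72 to 96 h (57.3% higher, main 92.7%), 144 for the strain at 6 h, 1 for phosphate at 6 h, 320 for glycerol at 6 h and 187 for the change of the strain difference (56.2% higher), and the share of higher genes in C3 over time became 49.6% (main 60.6%) and in late glycerol 69.0% (main 81.0%). In the change of the strain difference it turned cox1-i6 to 0.19 and Pfa1 to 1.20, and 75 of 82 values of named genes, each gene counted once per comparison, passed with the same sign. Normexp gave 135 from 24 to 48 h (41.5% higher, main 55.5%), 79 from 72 to 96 h (70.9% higher), 229 for the strain at 6 h (10% higher, main 50.1%), 450 for glycerol at 6 h (93.6% higher, main 55.8%), 176 for late glycerol and 179 for the change of the strain difference (93.9% higher, main 39.9%), and 74.3% higher in C3 from 72 to 120 h (main 61.1%). The brightest probe gave 69 for late phosphate and 68.0% higher in late glycerol. With no minimum fold, which by construction adds genes, the counts were 5485, 5438, 5156 and 5310 for C1 to C4 over time, 5856, 3599, 2892 and 4302 for the steps from 6 to 96 h, 3934 and 4778 for the steps of C3, 3236 and 2599 for the strain (6 h and late), 1 and 3376 for phosphate, 4039 and 3497 for glycerol and 2763 for the change of the strain difference. With an estimated correlation 5 of 65 list calls held.

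Without 96 h 88 genes passed for the strain (48.9% higher, main 86.5%) and 681 for glycerol, and C2 alone gave 1181 from 72 to 96 h (80.2% higher). Without the libraries of 6 to 72 h closest to another group 48 passed for phosphate at 6 h and 113 for late phosphate, with fewer samples. The scan day as a block gave 477 for the strain at 6 h (60.8% higher), 36 for the late strain comparison (75% higher) and 527 for the change of the strain difference (27.1% higher), and the slide as a random block gave 464 (76.7% higher) for the strain at 6 h, 717 (30.7% higher) for glycerol at 6 h and 543 (22.1% higher) for the change of the strain difference. The scan day was not run for 72 to 96 h and C3 from 72 to 120 h, where 1 scan day holds all late libraries. The mean signal planned for normexp is not in the files, so the median signal took its place.

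The replicate block moved no count by more than 1.5 times: it gave 618 from 72 to 96 h, 681 for the strain at 6 h, 37 for late phosphate and 269 for late glycerol.

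Leaving out each library gave 3463 to 3565 (C1), 3391 to 3432 (C2), 2864 to 2980 (C3) and 3104 to 3159 (C4) over time, 3157 to 3225, 245 to 272, 137 to 179 and 511 to 704 for the steps, 1365 to 1436 and 1693 to 2125 in C3, 599 to 831 and 35 to 39 for the strain, 0 to 14 and 32 to 49 for phosphate (14 at 6 h without C1 6 h C, fewer samples), 988 to 1229 and 248 to 305 for glycerol, and 566 to 746 for the change of the strain difference. Where 1 library of a group is left, limma assumes that it varies like the other groups. Signal over background limits dim genes: 93.9% of spots on the faintest array by this measure were well above background.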

Other observations

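The test of neighbouring genes was fixed first, and the genes without a list were chosen only after the result was seen.

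Some genes outside the lists, which carry only a tag here, moved far over time. In C2 between 6 and 72 h YALI0B21824g rose by 10.68 ± 0.36 and YALI0B21846g, close to it by number, by 9.94 ± 0.29, while YALI0B18194g fell by 8.65 ± 0.27 and YALI0D26081g fell by 8.18 ± 0.22 (SE, n = 3 and 3). In C3 from 72 to 120 h YALI0F28193g rose by 9.09 ± 0.31 and YALI0D07304g fell by 8.80 ± 0.19.

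Between C2 and Po1h at 24 to 96 h the tags YALI0F01584g (1.04), YALI0F01606g (1.57), YALI0F01628g (1.44) and YALI0F01650g (1.41), which follow each other by number, were all higher in C2, with YALI0F01320g at 1.51. Without 96 h, where the libraries labelled C4 carry the transgenes, they had 1.27, 1.51, 1.58, 1.56 and 2.14 in the same order. YALI0F01650g was also 1.32 higher in C2 than in C1, which is Af4 too, and 0.98 higher without 96 h, just short of the minimum of 1. Its difference is therefore not plainly one of strain. YALI0D18084g was lower in C2 than in Po1h at 6 h (-2.97) and at 24 to 96 h (-2.66, and -3.44 without 96 h).

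Genes next to each other on a chromosome may rise together. Among 5977 genes with a tag 2023 rose in C2 by 72 h, and 759 pairs of neighbours both rose, against a median of 686 and a highest of 756 in 10000 shuffles (1-sided permutation p = 0.0001, the smallest they can give). Neighbours that share a probe sequence or a duplicated origin were not separated, so the cause stays open.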
